A study of Homo sapiens with 52 samples.

How the data were processed

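Liver biopsies from 52 patients with chronic hepatitis C were profiled on Affymetrix expression arrays, 1 array per patient. Per the labels, tissue was kept in RNAlater at low temperature, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised. The authors deposited log2 values of 54613 probe sets, made with GCRMA, which corrects the background by probe sequence, normalises between arrays and summarises probe sets, and with Partek, per the submitters' processing notes. Versions and settings of both tools are not given in the sources used here. The deposited log2 values ran from 2.93 to 14.71, with array medians from 5.63 to 5.86, and were used without a further transformation. All 52 columns were matched to a sample, and 0 were identical to another.

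Groups followed the labels: 15 untreated, 14 IFN, 11 RBV and 12 IFN+RBV patients. Samples are named by group and replicate, and replicate numbers carry no order. The labels used here give no batch or date, so no batch term could be fitted.

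Probe sets were named from the annotation that accompanies the arrays: 41091 had 1 gene symbol, 1801 had several and 11721 had none. Probe sets with several names or none were left out of the gene tests and tested apart, since their signal cannot be given to 1 gene. For privacy, 59 sex-linked probe sets were left out of every test, which left 41032. Each of 19740 genes was represented by its probe set of highest mean over all arrays, and 18486 genes with a log2 value above 4 in at least 11 arrays, the size of the smallest group, were tested.

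A linear model with 4 group means was fitted to all arrays with limma 3.58.1 (lmFit and eBayes, 48 residual and 3.35 prior degrees of freedom) in R 4.3.3 with the data.table package (version 1.17.8). The 6 comparisons were IFN against untreated, RBV against untreated, IFN+RBV against RBV, IFN+RBV against IFN, ribavirin averaged over both peginterferon states, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "rose" and "fell" are used for called genes and lists. Fold changes are powers of the log2 difference, and SE is that of the moderated fit. The simulated data of the self-test had 18486 genes, 100 of them changed by 0.5 and 100 by 1, at the group sizes of the study. Noise was drawn independently for each gene and array, without the structure that the real arrays share. Recovery of simulated changes is therefore not the power of the study.

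The 30 gene lists were fixed before the data were examined, as were the comparisons, tests, filters and the rule for named genes. They cover antiviral ISGs, interferon signalling and sensing, feedback inhibitors, chemokines and cytokines, MHC class I, MHC class II, interferon-gamma responsive genes, acute phase proteins, drug metabolism, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, bile acids, purine metabolism, p53 targets, proliferation, iron and haem, red cell transcripts, the unfolded protein response, immediate early genes, heat shock proteins and 9 sets of cell-type markers. The score of a list was the mean log2 value of its tested members in each patient. Scores were compared by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05, permuting labels among the patients compared, ribavirin labels within peginterferon state for the average, and residuals of the additive model for the interaction. The p-values were adjusted over the 30 lists of a comparison. Members called were counted over all genes and adjusted over the list alone. Only 5 genes belong to more than 1 list, such as ATF3. The camera test of limma with an estimated correlation between genes, which compares a list with the other genes, was the alternative.

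Genes named in the text were 16 genes of a fixed panel of 17, the other not analysed here, the 10 largest rises and falls among called genes (passing over antisense and unnamed symbols, of which MAGI2-AS3 and JAKMIP2-AS1 are nevertheless given because they fell as far), the 5 of smallest p where none was called, and up to 4 members of smallest p per list. Other genes in the closing section were chosen after their values were seen.

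Alternatives were no filter, a filter at log2 above 6, the mean of all probe sets of a gene, probe sets counted singly, quantile normalization, median centring, array weights, eBayes with trend and robust options, T cell, bile duct and stellate marker scores as covariates, only the groups compared, a Wilcoxon test, a minimum size of 1 on the log2 scale, scaled members, the median over members, camera, the SD as measure of spread, and leaving out each array in turn. Added after the data were seen were leaving out the 7 arrays with a median correlation under 0.95 and using that correlation as a covariate. For each count of called genes, 100 random splits of the same arrays, the real one included, were fitted. The number of arrays limits the precision, and signals near the background of the arrays limit what dim genes can show.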

Results

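Gene expression was measured on Affymetrix arrays in liver biopsies from 52 patients with chronic hepatitis C, with 1 array per patient. The labels cross 2 treatments. Peginterferon alfa-2a is a long-acting interferon given by injection, and ribavirin is an oral guanosine analogue that inhibits IMP dehydrogenase, an enzyme of guanine nucleotide synthesis. The untreated group held 15 patients. The IFN group held 14 patients biopsied 6 h after the first peginterferon injection. The RBV group held 11 patients who had taken ribavirin for 4 weeks and had received no peginterferon at biopsy. The IFN+RBV group held 12 patients who had received both, with 4 weeks of ribavirin and a biopsy 6 h after peginterferon. The table gave log2 values from 2.93 to 14.71 for 54613 probe sets, with array medians between 5.63 and 5.86. Pairwise correlations between arrays ran from 0.863 to 0.989, and 7 arrays had a median correlation with the others under 0.95: 4 untreated, 2 IFN, 0 RBV and 1 IFN+RBV. The number of arrays limits the precision of every difference. Differences are on the log2 scale and refer to the 18486 genes tested.

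Peginterferon given without ribavirin was assessed by comparing the IFN patients with the untreated patients. CCL8, which encodes a chemokine that attracts monocytes, rose the most, by 3.70 (13-fold, SE 0.348, adjusted p = 1.22e-10), and lay above the untreated mean in 14 of 14 IFN patients. The antiviral GTPase gene MX2 rose by 2.77 (6.80-fold, SE 0.252, adjusted p = 8.29e-11), also in 14 of 14 patients, and RSAD2, which encodes the antiviral enzyme viperin, rose by 2.86 (7.25-fold, SE 0.510, adjusted p = 0.000393) in 13 of 14. The antiviral score, the mean log2 value per patient of 42 interferon-stimulated genes (ISGs), was 10.29 ± 0.77 (SD, n = 15) in untreated and 11.54 ± 0.58 (SD, n = 14) in IFN patients. It rose by 1.25 (SE 0.254, permutation p = 0.00011, adjusted p = 0.000825) and exceeded the untreated mean in 13 of 14 patients. The exception, IFN replicate 4 at 10.09, was also the array of lowest median correlation with the others (0.8925).

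**Figure D1:**
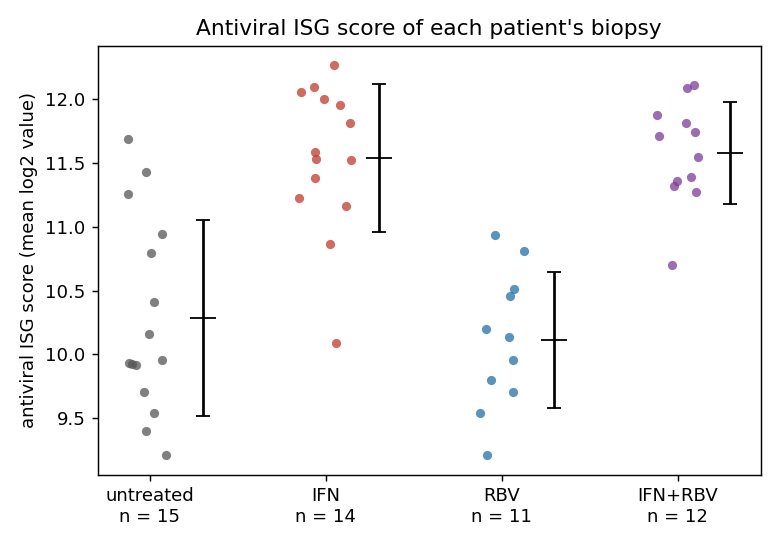
Mean log2 value of the 42 antiviral ISGs in each patient (points), by treatment group, with the group mean and 1 SD as bars. The group means are 10.29 in untreated, 11.54 in IFN, 10.12 in RBV and 11.58 in IFN+RBV patients.

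Across all genes, limma called 226 genes higher and 51 lower at an adjusted p under 0.05, and 110 of these differed by at least 1 on the log2 scale. The count was 323 higher and 166 lower with array weights, and 450 in all without IFN replicate 4. At an unadjusted p under 0.05 there were 2117 genes, 970 higher and 1147 lower, where 924 would be given by chance. In data simulated at these group sizes with independent noise, the same test recovered 83 of 100 changes of 1 and 42 of 100 changes of 0.5. The real arrays share structure that was not simulated, so recovery in them may differ. A fixed list held 63 of the 277 called genes, and 214 were in none.

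Most of the antiviral list moved. Of its 42 members, 31 rose over all genes tested and 37 when adjusted over the list alone. SAMD9L, which restricts viral protein synthesis, rose by 1.87 (adjusted p = 8.94e-10) and its neighbour SAMD9 by 1.68 (adjusted p = 8.7e-06). SP110, a nuclear body protein gene, rose by 1.34 (adjusted p = 1.23e-05), IFI44L by 2.34 (5.05-fold, adjusted p = 0.000608) and OAS3, which makes an activator of RNase L, by 2.10 (adjusted p = 0.00138). From the fixed panel, MX1 rose by 1.97 (adjusted p = 0.000288), IFIT1, which binds viral RNA, by 1.59 (adjusted p = 0.000685), OAS1 by 1.20 (adjusted p = 0.0078) and the ubiquitin-like ISG15 by 1.40 (adjusted p = 0.0424). IFI6 differed by 1.13 (adjusted p = 0.154) and IFI27 by 0.73 (adjusted p = 0.535), neither past the threshold.

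Some sensors of viral RNA rose alongside. In the list of 18 interferon signalling and sensing genes, the score rose by 0.55 (SE 0.108, permutation p = 3e-05, adjusted p = 3e-04), with 5 members called over all genes and 10 adjusted over the list alone. With the median over members the difference was 0.33 and not called (adjusted p = 0.11). IFIH1, the cytosolic RNA sensor MDA5, rose by 1.47 (adjusted p = 0.000187), the endosomal RNA sensor TLR7 by 1.30 (adjusted p = 0.00174), the transcription factor IRF7 by 1.25 (adjusted p = 0.00506) and the adaptor MYD88 by 0.53 (adjusted p = 0.0068). The RNA sensor RIGI differed by 1.56 without being called (adjusted p = 0.0742). IRF9, the DNA-binding part of the interferon-activated factor ISGF3, differed by 0.62 without reaching the threshold (adjusted p = 0.0606). The 12 feedback inhibitors of cytokine signalling rose by 0.35 as a score (SE 0.132, permutation p = 0.013, adjusted p = 0.0434), a call that was lost in the camera set test (adjusted p = 0.0999 with an estimated correlation) and in 6 other alternatives (adjusted p from 0.0572 to 0.104). Called members were USP18, which blocks the interferon receptor, at 1.5 (adjusted p = 0.00909) and the JAK inhibitor SOCS1 at 0.97 (adjusted p = 0.0137), and 3 members passed when adjusted over the list alone. SOCS3 differed by 0.88 (adjusted p = 0.195).

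Secreted immune mediators and genes best known from the interferon-gamma response formed a further group. The score of 25 chemokines and cytokines rose by 0.80 (SE 0.142, adjusted p = 0.00015, in 13 of 14 patients), with 7 called over all genes and 13 adjusted over the list alone. Besides CCL8, the monocyte chemokine CCL2 rose by 2.17 (adjusted p = 0.00109), the T cell chemokines CXCL11 and CXCL10 by 2.05 and 1.62 (adjusted p = 0.00534 and 0.0157), and the B cell survival factor TNFSF13B by 1.04 (adjusted p = 1.1e-08). The 13 interferon-gamma responsive genes rose by 0.90 as a score (SE 0.138, adjusted p = 0.00015) in 14 of 14 patients, and 6 were called (10 adjusted over the list alone). They included the guanylate-binding proteins GBP5 at 1.59 (adjusted p = 2.39e-05), GBP4 at 1.60 (adjusted p = 0.00015) and GBP1 at 1.29 (adjusted p = 0.00035). The Fc receptor gene FCGR1A rose by 1.64 (adjusted p = 0.000602) and its relative FCGR1BP by 2.16 (adjusted p = 8.7e-06), but their probe sets may share signal, so which of the pair changed is uncertain. Unadjusted p-values of both list scores were 1e-05, the smallest that the permutations can give.

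The score of class I antigen processing genes rose and that of class II genes was not called. The class I score of 18 genes rose by 0.44 (SE 0.126, adjusted p = 0.0107), a call lost with an estimated correlation (adjusted p = 0.0587), scaled members (adjusted p = 0.0516) and the median over members (adjusted p = 0.181), and 3 members were called (7 adjusted over the list alone): the peptide transporters TAP1 at 0.90 (adjusted p = 0.00103) and TAP2 at 1.28 (adjusted p = 0.00109) and the class I activator NLRC5 at 0.92 (adjusted p = 0.0185). The class II score differed by 0.40 (SE 0.20, adjusted p = 0.154) with 0 of 12 members called by limma over all genes; HLA-DRA differed by 1.09 (adjusted p = 0.439), with HLA probe sets open to shared signal. Among genes outside the fixed lists, the phospholipid transporter gene ATP10A rose by 2.25 (SE 0.386, adjusted p = 0.000247) and CD274, which encodes the checkpoint ligand PD-L1, by 2.04 (SE 0.379, adjusted p = 0.000685).

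Stress and rapid response genes were also higher. The 18 immediate early and NF-kB genes, which tissue handling also moves, rose by 0.64 as a score (SE 0.147, adjusted p = 0.00132) in 13 of 14 patients, with 6 called and 10 adjusted over the list alone. Examples are the transcription factors ATF3 at 1.66 (SE 0.281, adjusted p = 0.00019), JUN at 1.40 (adjusted p = 0.0305) and KLF4 at 0.87 (adjusted p = 0.023) and the survival gene IER3 at 0.92 (adjusted p = 0.0406). ATF3 also belongs to the list of 20 unfolded protein and integrated stress response genes, whose score rose by 0.25 (SE 0.0848, adjusted p = 0.027). That call was lost with an estimated correlation (adjusted p = 0.104), with the median over members (difference 0.03, adjusted p = 0.952), the mean of all probe sets (adjusted p = 0.14), median centring (adjusted p = 0.0789), scaled members (adjusted p = 0.122) and cell-type marker covariates (adjusted p = 0.114). The other called member was the folate enzyme gene MTHFD2 at 1.07 (adjusted p = 0.0316). The ER chaperone gene HSPA5 differed by 0.48 (adjusted p = 0.32). Heat shock proteins, which tissue handling also moves, differed by 0.30 as a score (adjusted p = 0.214). They were called higher with array weights (0.37, adjusted p = 0.0113), without the 7 arrays of low correlation (0.34, adjusted p = 0.0349) and with the correlation covariate (0.28, adjusted p = 0.0392).

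Fatty acid synthesis was lower as a score, while cholesterol synthesis was not called. The score of 16 fatty acid synthesis genes fell by 0.23 (SE 0.0733, permutation p = 0.00417, adjusted p = 0.0179) and lay below the untreated mean in 12 of 14 patients. The call was lost with an estimated correlation (adjusted p = 0.113), with the median over members in place of the mean (difference -0.05, adjusted p = 0.781) and without the 7 arrays of low correlation (difference -0.22, adjusted p = 0.0699). By limma, 0 of its genes were called over all genes or adjusted over the list alone, although 15 of 16 had differences below 0. THRSP, a regulator of lipogenesis, differed by -0.40 (adjusted p = 0.171), the elongase ELOVL6 by -0.42 (adjusted p = 0.277), the desaturase FADS2 by -0.59 (adjusted p = 0.316) and the acyltransferase GPAM by -0.36 (adjusted p = 0.343).

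The largest single falls came from genes of mixed function. PITPNM3, a phosphatidylinositol transfer protein gene, fell by 1.23 (SE 0.157, adjusted p = 9.38e-07), and TOX2, a transcription factor gene of lymphocytes, fell by 1.07 (SE 0.205, adjusted p = 0.00109); both lay below the untreated mean in 14 of 14 patients. The DNA methylation cofactor DNMT3L fell by 1.21 (adjusted p = 0.00655), the lectin pseudogene CLEC4GP1 by 1.21 (adjusted p = 0.0407), the beta-1 adrenoceptor ADRB1 by 1.08 (adjusted p = 0.02) and TRABD2B, a Wnt-cleaving protease gene, by 1.02 (adjusted p = 0.0381). The remaining 4 of the 10 largest falls were CD244, a receptor of NK cells, SMCO3, AKAP19 and ANKRD55, at -0.99, -0.98, -0.97 and -0.97 (adjusted p = 0.0121, 0.0121, 0.0266 and 0.00571). The nucleoside carrier SLC28A1 fell by 0.67 (adjusted p = 0.0366), the only called member of the 29 purine metabolism and nucleoside transport genes, whose score differed by -0.06 (adjusted p = 0.445). IMPDH2, the target enzyme of ribavirin, differed by -0.31 (adjusted p = 0.277), the nucleoside carrier SLC29A1 by -0.17 (adjusted p = 0.708) and HAMP, the gene of the iron hormone hepcidin, by 0.56 (adjusted p = 0.32).

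Cell-type markers gave no called score in this comparison. Differences were -0.02 for hepatocyte (adjusted p = 0.924), 0.48 for bile duct (adjusted p = 0.0958), 0.29 for stellate cell and matrix (adjusted p = 0.253), 0.15 for T cell (adjusted p = 0.654), 0.26 for NK and cytotoxic (adjusted p = 0.386), 0.01 for B and plasma cell (adjusted p = 0.960), 0.26 for macrophage (adjusted p = 0.434), 0.10 for neutrophil (adjusted p = 0.643) and -0.01 for endothelial markers (adjusted p = 0.960). The perforin gene PRF1 was the only called marker, at 0.73 (adjusted p = 0.0376). The remaining lists were not called either: acute phase proteins at 0.10 (adjusted p = 0.424), drug-metabolising enzymes at 0.02 (adjusted p = 0.954), cholesterol synthesis at -0.02 (adjusted p = 0.954), fatty acid oxidation at 0.07 (adjusted p = 0.654), bile acid genes at -0.07 (adjusted p = 0.654), p53 targets at -0.02 (adjusted p = 0.954), proliferation at -0.01 (adjusted p = 0.960), iron and haem handling at 0.07 (adjusted p = 0.471) and red cell transcripts at 0.06 (adjusted p = 0.654). In all, 9 of 30 lists passed. The antiviral, signalling, chemokine, interferon-gamma and immediate early lists, 5 in number, kept their calls with an estimated correlation.

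Peginterferon given on top of ribavirin was assessed by comparing IFN+RBV with RBV patients. CCL8 rose by 3.79 (13.9-fold, SE 0.391, adjusted p = 2.95e-09) and MX2 by 3.17 (9.02-fold, SE 0.283, adjusted p = 3.78e-11), and both lay above the RBV mean in 12 of 12 IFN+RBV patients. ISG15 rose by 2.36 (5.11-fold, SE 0.429, adjusted p = 0.00113), also in 12 of 12. The antiviral score went from 10.12 ± 0.54 (SD, n = 11) to 11.58 ± 0.40 (SD, n = 12), a rise of 1.47 (SE 0.196, adjusted p = 3e-04) seen in 12 of 12 patients. Its unadjusted p of 1e-05 was the smallest that the permutations can give. LYVE1, a hyaluronan receptor of liver sinusoidal and lymphatic endothelium, fell by 1.36 (SE 0.337, adjusted p = 0.0267) in 11 of 12 patients.

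Over all genes, limma called 128 higher and 29 lower, 92 of them by at least 1, and 1592 genes had an unadjusted p under 0.05, 860 higher and 732 lower. With array weights 255 were called higher and 123 lower. Recovery of simulated changes was 78 of 100 at 1 and 33 of 100 at 0.5. Fixed lists held 47 of the 157 called genes. Among antiviral genes 32 of 42 rose, and 39 when adjusted over the list alone: SAMD9 rose by 2.08 (adjusted p = 1.15e-06), SAMD9L by 1.88 (adjusted p = 3.61e-08), MX1 by 2.33 (adjusted p = 0.00026), RSAD2 by 2.61 (adjusted p = 0.00794), IFI44L by 2.25 (adjusted p = 0.00651) and LAMP3, a lysosomal protein gene, by 2.54 (adjusted p = 0.00325). The kinase gene EIF2AK2, which halts translation on double-stranded RNA, rose by 1.02 (adjusted p = 8.68e-06). From the panel, IFIT1 rose by 1.62 (adjusted p = 0.00381), OAS1 by 1.62 (adjusted p = 0.00162) and IFI6 by 1.76 (adjusted p = 0.0214), and IFI27 differed by 1.12 (adjusted p = 0.438). Outside the lists, ATP10A rose by 2.59 (adjusted p = 0.000261) and MAB21L2, a developmental gene, by 2.22 (adjusted p = 0.0144).

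Some sensing and feedback genes rose here too. The signalling and sensing score rose by 0.55 (SE 0.108, adjusted p = 0.00075) in 12 of 12 patients, with 4 members called (7 adjusted over the list alone): the RNA sensors RIGI at 2.17 (adjusted p = 0.0174), IFIH1 at 1.58 (adjusted p = 0.000602) and TLR7 at 1.51 (adjusted p = 0.00229), and IRF7 at 1.61 (adjusted p = 0.00162). IRF9 differed by 0.44 (adjusted p = 0.489). Feedback inhibitors rose by 0.47 as a score (SE 0.112, adjusted p = 0.003), lost with an estimated correlation (adjusted p = 0.0747), and the called members were USP18 at 1.78 (adjusted p = 0.00683) and SOCS1 at 1.01 (adjusted p = 0.0394), with 4 adjusted over the list alone. SOCS3 differed by 1.03 (adjusted p = 0.193). Chemokines and cytokines rose by 0.66 as a score (SE 0.186, adjusted p = 0.0098) in 11 of 12 patients; the 3 called over all genes were CCL8, CXCL11 at 2.25 (adjusted p = 0.00956) and TNFSF13B at 0.91 (adjusted p = 1.22e-05), and 5 passed when adjusted over the list alone. The list call was lost with the median over members (difference 0.63, adjusted p = 0.0715). CXCL10 differed by 1.30 (adjusted p = 0.206). The interferon-gamma score rose by 0.71 (SE 0.177, adjusted p = 0.00348), with GBP1 called at 1.19 (adjusted p = 0.00678) and 10 of 13 adjusted over the list alone.

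The class I score differed by 0.31 (SE 0.116, adjusted p = 0.0501). It was called in 5 alternatives: the mean of all probe sets (adjusted p = 0.0379), quantile normalization (adjusted p = 0.016), median centring (adjusted p = 0.0429), without the 7 arrays (adjusted p = 0.0492) and with the correlation covariate (adjusted p = 0.0145). With the reported choices, TAP1, TAP2 and NLRC5 rose by 1.05, 1.45 and 1.18 (adjusted p = 0.00125, 0.00162 and 0.00673) and 4 members passed when adjusted over the list alone. Class II differed by -0.19 (adjusted p = 0.534), but was called lower with cell-type marker scores as covariates (-0.46, adjusted p = 0.0248). Immediate early genes, which tissue handling also moves, rose by 0.44 as a score (SE 0.142, adjusted p = 0.0239), with ATF3 called at 1.38 (adjusted p = 0.012) and 4 adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.0747), with the median over members (adjusted p = 0.088) and with cell-type marker scores as covariates (adjusted p = 0.107). The unfolded protein score differed by 0.18 (adjusted p = 0.0633) and heat shock proteins by 0.19 (adjusted p = 0.261). With the correlation covariate both were called higher (0.20 and 0.33, adjusted p = 0.0437 and 0.01), and the unfolded protein score also with array weights (0.20, adjusted p = 0.0332). Fatty acid synthesis differed by 0.03 (adjusted p = 0.902).

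Scores of 2 cell types passed the threshold. Bile duct markers rose by 0.84 as a score (SE 0.300, permutation p = 0.0121, adjusted p = 0.0454) in 9 of 12 patients, with 0 of 12 members called by limma over all genes and 5 adjusted over the list alone. The list call was lost with an estimated correlation (adjusted p = 0.0747) and with the median over members (difference 1.22, adjusted p = 0.0732). The epithelial adhesion gene EPCAM differed by 2.31 (SE 0.710, adjusted p = 0.128), the chloride channel CFTR by 1.49 (SE 0.483, adjusted p = 0.161), the matrix protease MMP7 by 1.07 (adjusted p = 0.268) and the progenitor factor SOX9 by 1.16 (adjusted p = 0.279). Endothelial markers fell by 0.36 as a score (SE 0.0705, permutation p = 1e-04, adjusted p = 0.001) in 12 of 12 patients, and 15 of 18 members lay below 0. With an estimated correlation this call was lost (adjusted p = 0.0747). LYVE1 was the member called over all genes and adjusted over the list alone. The scavenger receptor STAB2 differed by -0.64 (adjusted p = 0.268), and the lectins CLEC4G and FCN2 by -0.48 and -0.60 (adjusted p = 0.379 and 0.383).

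Falls outside the lists were led by MROH2A at -2.17 (SE 0.545, adjusted p = 0.0292), the esterase CES5A at -1.77 (SE 0.377, adjusted p = 0.0062), JAKMIP2 at -1.66 (adjusted p = 0.00491), the antisense transcripts MAGI2-AS3 at -1.55 (adjusted p = 0.00794) and JAKMIP2-AS1 at -1.54 (adjusted p = 0.0062), the somatostatin receptor SSTR1 at -1.32 (adjusted p = 0.0144) and the hydroxy acid receptor HCAR3 at -1.30 (adjusted p = 0.00298). CES5A lay below the RBV mean in 12 of 12 patients. Smaller falls were those of SYT9 at -1.07 (adjusted p = 0.041), the dipeptidase DPEP2 at -0.99 (adjusted p = 0.0062), SIGIRR, which dampens interleukin-1 receptor signalling, at -0.91 (adjusted p = 0.0277), and IRAG2 at -0.90 (adjusted p = 0.0198). HAMP differed by -0.02 (adjusted p = 0.998), IMPDH2 by -0.32 (adjusted p = 0.429) and SLC29A1 by -0.33 (adjusted p = 0.626). The other lists were not called, with differences from -0.16 for red cell transcripts (adjusted p = 0.304) to 0.33 for stellate cell and matrix genes (adjusted p = 0.197), among them purine genes at -0.09 (adjusted p = 0.154) and T cell markers at 0.05 (adjusted p = 0.940). With cell-type marker scores as covariates, purine genes were called lower (-0.14, adjusted p = 0.0087). Bile acid genes (-0.22, adjusted p = 0.00795) and drug-metabolising enzymes (-0.14, adjusted p = 0.032) were also called lower with these covariates. The bile duct score, which is among the covariates, itself rose in this comparison. With them the number of genes at an unadjusted p under 0.05 by limma went from 1592 to 3106. The adjustment may therefore contribute to these calls and to that of class II. In all, 8 of 30 lists passed, and 4 of them kept the call with an estimated correlation: antiviral, signalling (adjusted p = 0.0301), chemokine and interferon-gamma (both adjusted p = 0.0107).

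**Figure D2:**
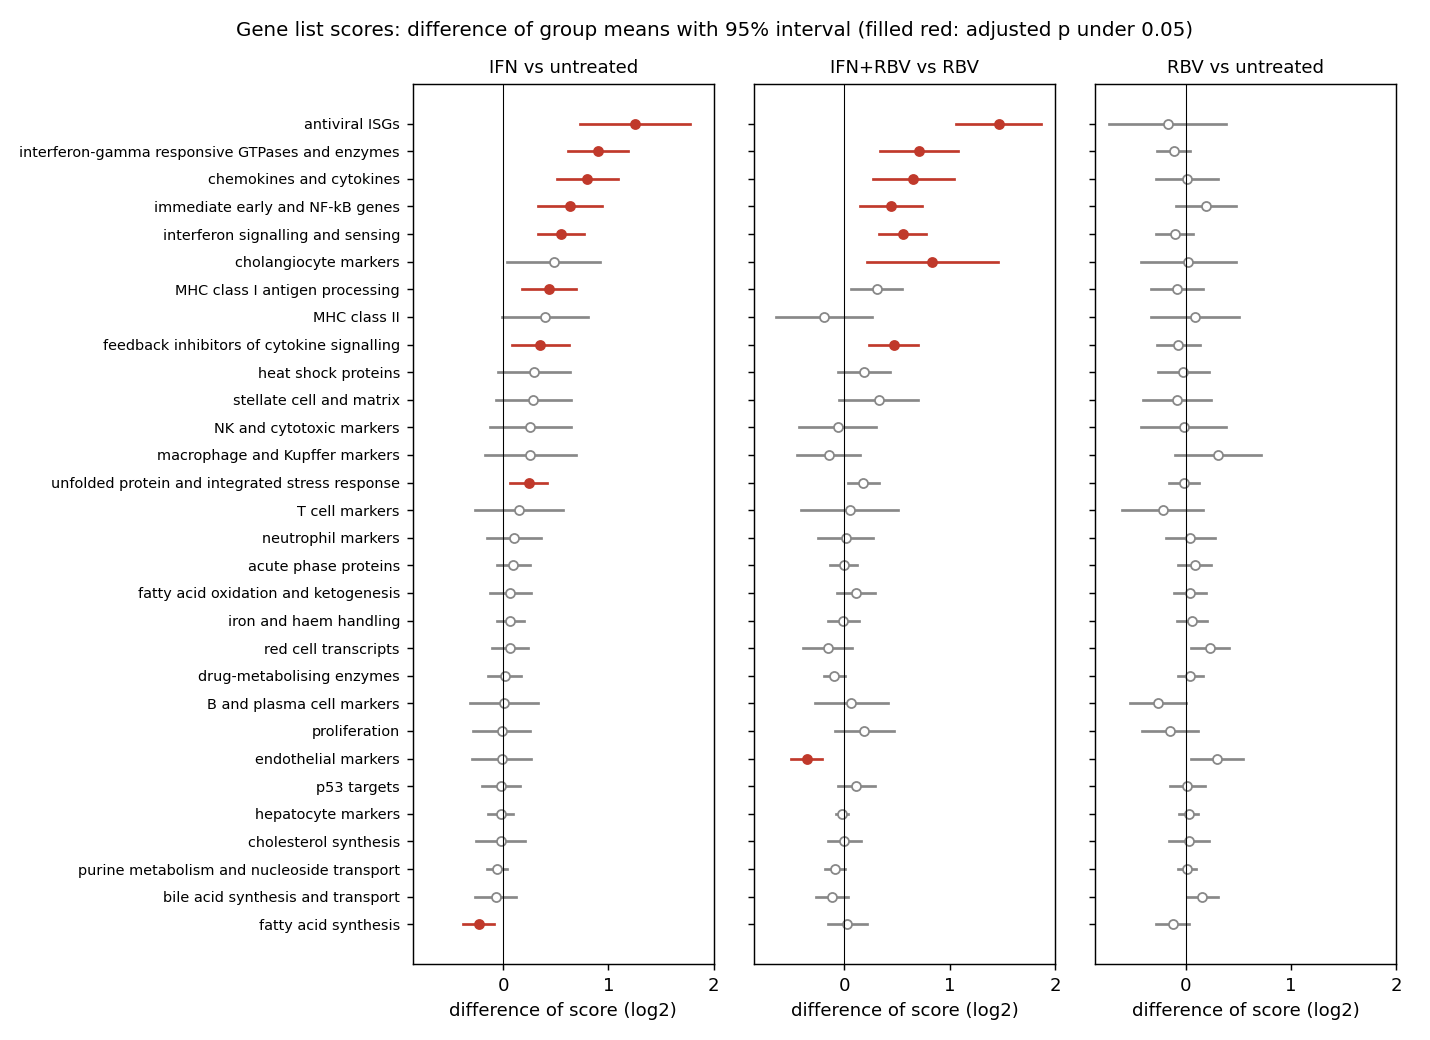
Differences in list score (log2) for the 30 gene lists in the IFN vs untreated, RBV vs untreated and IFN+RBV vs RBV comparisons, with 95% intervals, where filled red points mark an adjusted p under 0.05. Of the 30 lists, 9, 0 and 8 passed.

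Both peginterferon responses, measured in separate patients, shared 92 rising genes, where 1.56 would be shared by chance, and 4 falling genes, where 0.08 would be. No gene was called in opposite directions, and 338 were called in at least 1 of the comparisons. The sign was the same in the other comparison for 272 of the 277 genes called without ribavirin (98.2%) and for 155 of the 157 called with it (98.7%). Across all genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.355 and a Spearman correlation of 0.0774.

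**Figure D3:**
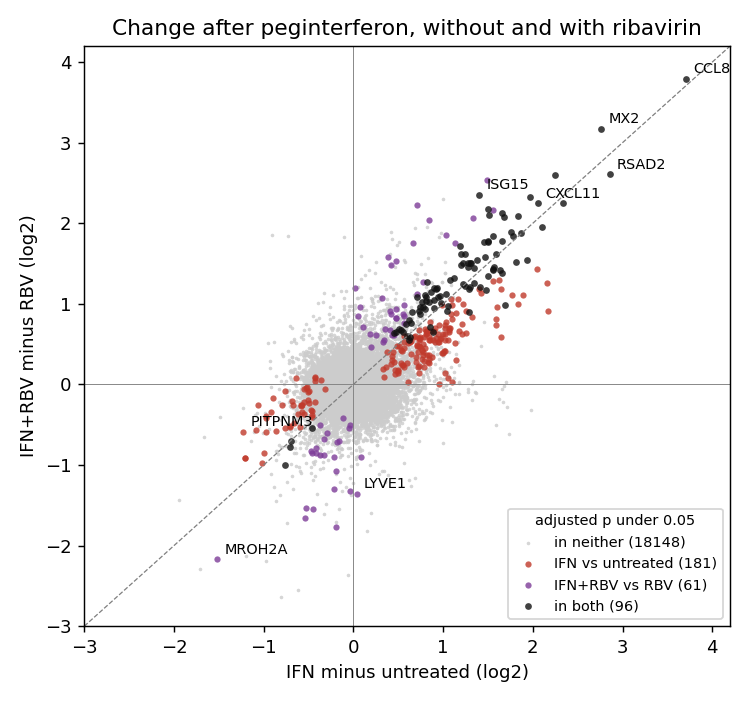
Log2 difference of each of 18486 genes after peginterferon without ribavirin (IFN minus untreated, horizontal axis) and with ribavirin (IFN+RBV minus RBV, vertical axis), coloured by where the gene was called, with the line of identity dashed. Both differences had the same sign for the 96 genes called in both, 181 were called only without and 61 only with ribavirin.

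Whether ribavirin altered the response to peginterferon was tested as the interaction, the response with ribavirin minus that without. The antiviral score responded by 0.21 more with ribavirin (SE 0.335, adjusted p = 0.868), and limma called 0 of 18486 genes (smallest adjusted p = 0.779), with 824 at an unadjusted p under 0.05. That number was 467 without the 7 arrays of low correlation, 1719 with array weights and 2845 with cell-type marker scores as covariates, with 0 genes called in each. No Wilcoxon test was run for an interaction. ISG15 had an interaction of 0.95 (SE 0.575, adjusted p = 0.779), LYVE1 of -1.39 (SE 0.452, adjusted p = 0.779) and HAMP of -0.59 (SE 0.352, adjusted p = 0.779), none past the threshold. The other panel genes lay between -0.32 for CXCL10 and 0.62 for IFI6: IFIT1 at 0.03, SOCS1 at 0.04, SOCS3 at 0.16, CXCL11 at 0.19, USP18 at 0.29, MX1 at 0.36, IFI27 at 0.39, OAS1 at 0.42, IMPDH2 at -0.01, SLC29A1 at -0.17, IRF9 at -0.18 and RSAD2 at -0.25. The 5 genes of smallest p were TCF15 at -0.57, GADD45G at 1.18, APTR at -0.81, ARHGAP35 at 0.51 and ELFN2 at 2.57 (adjusted p = 0.779 each). Of the 30 lists 0 passed. Those of smallest p were fatty acid synthesis at 0.26 (SE 0.114, permutation p = 0.0237), endothelial markers at -0.34 (SE 0.165, permutation p = 0.0366) and class II at -0.59 (SE 0.298, permutation p = 0.0474), with an adjusted p of 0.474 each. Lists called in only 1 of the peginterferon comparisons were therefore not shown to respond differently with ribavirin. In data simulated with independent noise an interaction of 1 was recovered for 53 of 100 genes and an interaction of 0.5 for 11 of 100.

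Ribavirin without peginterferon was assessed in the RBV and untreated patients. SLC16A4, a gene of the monocarboxylate transporter family, rose by 1.74 (3.35-fold, SE 0.330, adjusted p = 0.0479) and lay above the untreated mean in 11 of 11 RBV patients. Its group means were 7.94 untreated, 9.68 RBV, 8.50 IFN and 8.71 IFN+RBV, and it differed by 0.21 between IFN+RBV and IFN patients (adjusted p = 1). The gene was no longer called after any of several other choices of processing, including leaving out the 7 arrays of low correlation, of which 4 were untreated and 0 were RBV. The antiviral score differed by -0.17 (SE 0.270, permutation p = 0.527, adjusted p = 0.878). Endothelial markers differed by 0.30 (SE 0.118, permutation p = 0.0116, adjusted p = 0.174), above the untreated mean in 11 of 11 patients, and red cell transcripts by 0.23 (SE 0.0870, permutation p = 0.00783, adjusted p = 0.174) in 8 of 11; neither passed.

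SLC16A4 was the only gene that limma called, a Wilcoxon test called 2, and limma with array weights called 274 higher and 131 lower. An unadjusted p under 0.05 was reached by 3093 genes, 1889 higher and 1204 lower, where chance would give 924, and without the 7 arrays by 908. Recovery of simulated changes was 81 of 100 at 1 and 36 of 100 at 0.5. Endothelial genes KDR, LYVE1 and CLEC1B differed by 0.98, 0.98 and 0.83 (SE 0.294, 0.321 and 0.247; adjusted p = 0.209 each), and 5 of the 18 markers were higher when adjusted over the list alone. The haemoglobin genes HBB and HBD differed by 0.92 and 0.91 (adjusted p = 0.241 and 0.209). Within purine metabolism, the purine nucleoside phosphorylase PNP differed by 0.64, the nucleotide synthesis enzyme PRPS2 by 0.36 and the AMP deaminase AMPD2 by -0.50 (adjusted p = 0.209, 0.209 and 0.213), and the list of 29 by 0.01 (adjusted p = 0.935). Other genes of small p were the acetyltransferase NAT2 at 0.81, the transferrin receptor TFRC at -0.70 and RIGI at -1.24 (adjusted p = 0.209, 0.209 and 0.223).

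Panel genes were not called after ribavirin alone. ISG15 differed by -0.89 (SE 0.408, adjusted p = 0.271), HAMP by 0.64 (SE 0.250, adjusted p = 0.223) and IMPDH2 by 0.22 (SE 0.132, adjusted p = 0.382). CXCL11 differed by -0.56, MX1 by -0.45, IFI6 by -0.39, RSAD2 by 0.34, SOCS3 by -0.30, OAS1 by -0.29, IRF9 by 0.21, SLC29A1 by 0.18, IFIT1 by 0.11, SOCS1 by -0.07, IFI27 by -0.03, CXCL10 by 0.03 and USP18 by -0.01 (adjusted p from 0.528 to 0.995). Among the lists, bile acid genes differed by 0.16 (SE 0.0712, permutation p = 0.0343, adjusted p = 0.343), B and plasma cell markers by -0.27 (SE 0.130, adjusted p = 0.39), macrophage markers by 0.31 (SE 0.196, adjusted p = 0.641), T cell markers by -0.22 (adjusted p = 0.674), immediate early genes by 0.19 (adjusted p = 0.641), proliferation by -0.15 (adjusted p = 0.674) and p53 targets by 0.02 (adjusted p = 0.935). Of the 30 lists 0 passed, and the camera test gave an adjusted p of 0.993.

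**Figure D4:**
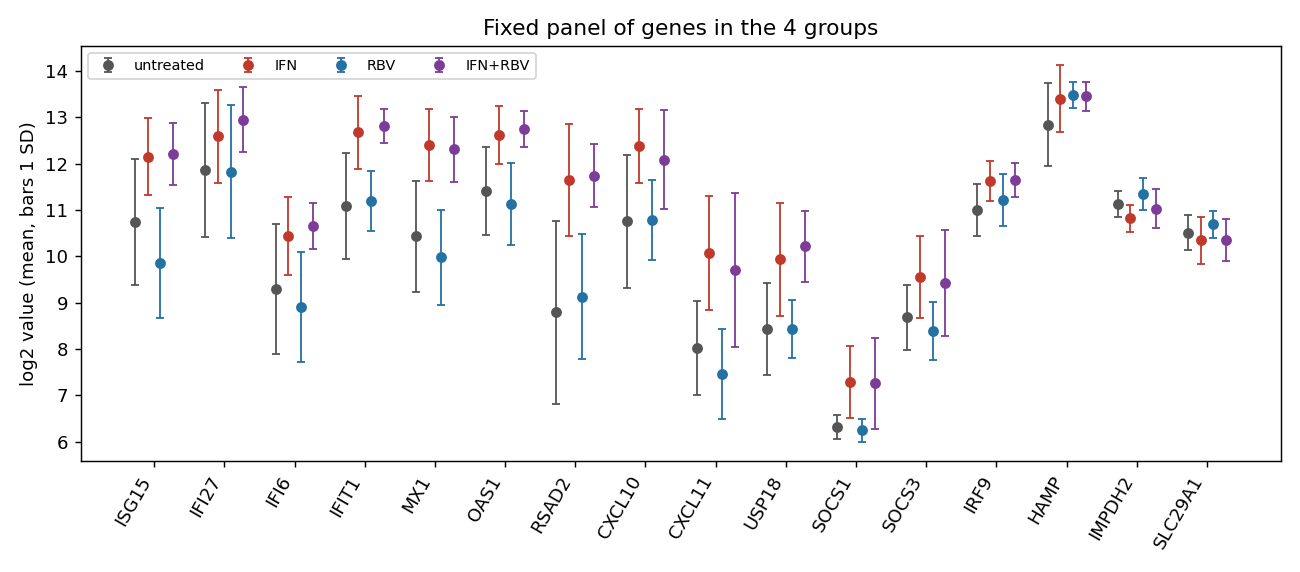
Mean log2 value of 16 panel genes in the 4 groups, with 1 SD as bars. MX1 and RSAD2 were called higher in IFN than in untreated and in IFN+RBV than in RBV patients, and no panel gene was called between RBV and untreated or between IFN+RBV and IFN patients.

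Ribavirin in patients biopsied after peginterferon was assessed by comparing IFN+RBV with IFN. The antiviral scores of 11.58 and 11.54 differed by 0.04 (SE 0.199, adjusted p = 0.908). Class II genes differed by -0.50 (SE 0.218, permutation p = 0.0305, adjusted p = 0.732), below the IFN mean in 10 of 12 patients, and NK markers by -0.34 (permutation p = 0.0612). The class II member HLA-DQA1 by itself differed by -2.38 (SE 1.37), with SDs from 3.3 to 3.93 within the 4 groups. Differences between patients in this gene can therefore move the class II score. limma called 0 genes (smallest adjusted p = 1), a Wilcoxon test called 0, and 804 genes had an unadjusted p under 0.05, where chance would give 924. That number was 1150 with cell-type marker scores as covariates, 1358 without the 7 arrays of low correlation, 1397 with array weights and 1508 with the median correlation as a covariate, with 0 genes called in each. Panel genes ran from -0.37 for CXCL11 to 0.36 for IFI27, with ISG15 at 0.07, IFI6 at 0.23, IFIT1 at 0.13, MX1 at -0.09, OAS1 at 0.13, RSAD2 at 0.09, CXCL10 at -0.29, USP18 at 0.28, SOCS1 at -0.04, SOCS3 at -0.14, IRF9 at 0.03, HAMP at 0.05, IMPDH2 at 0.21 and SLC29A1 at 0.01. The genes of smallest p, RHCG at 0.48, ZNF782 at 0.49, TUBE1 at 0.41, NHLH2 at 0.29 and GSTM1 at -2.07 (SE 0.594), had an adjusted p of 1 each, and GSTM1 shares sequence with the other GSTM genes. When adjusted over the list alone, IDO1 was lower in the interferon-gamma list. Of the 30 lists 0 passed. Simulated changes of 1 were recovered for 80 of 100 genes and of 0.5 for 36 of 100.

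Averaging the ribavirin difference over patients without and with peginterferon used all 52 arrays. The antiviral score differed by -0.07 (SE 0.168, adjusted p = 0.831). limma called 0 genes (smallest adjusted p = 0.148), and 2552 had an unadjusted p under 0.05, 1634 higher and 918 lower. With array weights limma called 272, and no Wilcoxon test was run for this average. CREBL2, a regulator of adipogenesis, differed by 0.26 (SE 0.0534, adjusted p = 0.148), PREPL by 0.52 (SE 0.109, adjusted p = 0.148) and CD36, a fatty acid transporter, by 0.59 (SE 0.137, adjusted p = 0.157), followed by ZNF572 at 0.51 and COX7A2L at 0.35 (adjusted p = 0.157 each). Panel genes lay between -0.47 for CXCL11 and 0.34 for HAMP, with ISG15 at -0.41, MX1 at -0.27, SOCS3 at -0.22, CXCL10 at -0.13, IFI6 at -0.08, OAS1 at -0.08, SOCS1 at -0.06, SLC29A1 at 0.09, IFIT1 at 0.12, IRF9 at 0.12, USP18 at 0.14, IFI27 at 0.17, IMPDH2 at 0.22 and RSAD2 at 0.22. Of the 30 lists 0 passed: bile acid genes differed by 0.14 and B and plasma cell markers by -0.24 (permutation p = 0.0293 and 0.0437), and class I genes by -0.14 (adjusted p = 0.524 each), with 2 class I members lower when adjusted over the list alone.

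Whether patients varied less in their antiviral score with ribavirin was tested on the mean absolute deviation from the group median. It was 0.43 in RBV and 0.60 in untreated patients (difference -0.18, permutation p = 0.318), and 0.31 in IFN+RBV and 0.43 in IFN patients (difference -0.11, permutation p = 0.387), so neither difference passed. Deviations after peginterferon, added after the values were seen, differed by -0.18 from those of untreated patients (permutation p = 0.302) and by -0.11 from those on ribavirin alone (permutation p = 0.285). The adjusted p was 0.387 for all 4. No paired analysis was possible because each patient gave 1 array, and replicate numbers are only names.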

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

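Tests of bile duct keratins against other bile duct markers and of PECAM1, VWF, PLVAP and EMCN against other endothelial markers, and the settings without the 7 arrays of low correlation, were chosen only after the results were seen.

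The difference between the peginterferon responses with and without ribavirin had an unadjusted permutation p under 0.05 for 3 of the 30 gene lists. Class II genes responded by -0.5905 relative to the response without ribavirin (SE 0.298, p = 0.0474), fatty acid synthesis genes by 0.2608 (SE 0.114, p = 0.0237) and endothelial markers by -0.3438 (SE 0.165, p = 0.0366). None passes adjustment over the 30 lists (adjusted p = 0.474 each). By gene, the class II members HLA-DQA1 and HLA-DRA had -1.84 and -1.56 (adjusted p = 0.801 and 0.779 by limma), the fatty acid synthesis genes AACS, FADS2 and THRSP 0.71, 0.70 and 0.39, and the endothelial LYVE1 -1.39 (adjusted p = 0.779 for each of these 4). HLA-DQA1 varied widely between patients within every group (SD from 3.3 to 3.93), so its value may follow which patients each group held.

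Probe sets that carry several gene names or none, which no comparison of the report uses, also responded. Of 11857 tested, 30 passed in IFN against untreated patients (27 higher and 3 lower, 26 of them unnamed) and 12 in IFN+RBV against RBV patients (11 higher and 1 lower, 11 of them unnamed). The largest differences were 2.27 and 2.11, and 6 probe sets were higher in both. In RBV against untreated patients 1 passed, at -1.13.

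The first pattern weighed is the excess of small p-values in RBV against untreated patients, 3093 genes at an unadjusted p under 0.05 against 924 by chance, with 1 gene called. Of 100 splits of the same arrays, 3 gave as many such genes as the real one (real value 3093, highest other 6068) and 3 called at least as many (real value 1, highest other 2199); so many calls in a random split point to a structure of the samples unrelated to treatment. That structure may be array quality: without the 7 arrays of low correlation, 4 of them untreated and 0 RBV, 908 genes remained, while leaving out as many random arrays of the same groups lowered the count that far in 2 of 100 draws, the real one included (others 745 to 5854, median 3046), but with the median correlation as a covariate 1806 genes remained and with array weights, which give those arrays less weight, the number was 5035, so array quality is not settled as the whole cause. Cell composition stays open. With T cell, bile duct and stellate scores as covariates 2433 genes remained. This cannot decide, because those scores differed little between RBV and untreated patients (6.70 and 6.92, 7.46 and 7.43, 8.96 and 9.04). Endothelial scores (9.43 in RBV and 9.13 in untreated patients) and macrophage scores (10.48 and 10.17) were not among the covariates. The covariates used brought the averaged ribavirin comparison from 2552 to 988 genes. A ribavirin effect smaller than this design can call stays open, as does an uneven share of poor arrays between the groups.

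The second pattern is the higher bile duct score in IFN+RBV than in RBV patients (0.84, SE 0.300), not called with an estimated correlation (adjusted p = 0.0747). Of the 23 arrays compared only 1, an IFN+RBV array, was among the 7 of low correlation, and it is argued against as the cause because the difference without it was 0.9226 (adjusted p = 0.0253). More bile duct tissue in the biopsies stays open: the keratins KRT7 and KRT19 differed from the other bile duct markers by -0.6122 (95% interval -1.112 to -0.112, p = 0.0205), which this explanation would not give, but both lie near the background (mean log2 5.91 and 5.50, against 8.18 for the other members), and the test was read as undecided for that reason after its value was seen, although MMP7, as dim at 5.59, differed by 1.07. By themselves KRT7 and KRT19 differed by 0.33 (p = 0.0614). A direct effect of peginterferon on EPCAM, CFTR and SOX9 in cells other than bile duct was not tested.

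The third pattern is the lower endothelial score in IFN+RBV than in RBV patients (-0.36, SE 0.0705), not called with an estimated correlation (adjusted p = 0.0747). The same single array of low correlation is argued against as the cause (-0.3365 without it, adjusted p = 9e-04). Less endothelium of every kind stays open. PECAM1, VWF, PLVAP and EMCN differed from the other members by 0.6544 (95% interval 0.0764 to 1.232, permutation p = 0.0295), which an equal fall of all members would not give. By themselves they differed by 0.15 (SE 0.213, permutation p = 0.479). The other members also hold genes not confined to sinusoids, such as CDH5 and TIE1, so the contrast cannot separate kinds of endothelium cleanly. PLVAP and VWF are dim (mean log2 5.85 and 6.50), unlike PECAM1 and EMCN (11.68 and 7.85). As for the keratins, the test was read as undecided after its value was seen. The other members, mostly of liver sinusoids, differed by -0.50 (p = 0.00012) in this comparison and by 0.41 in RBV against untreated patients (p = 0.01), so a high level in the RBV group enters the contrast. A fall in sinusoidal markers after peginterferon on ribavirin, or a rise on ribavirin alone that the IFN+RBV patients did not share, stay open.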

How the results depend on the processing

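Leaving out the 7 arrays of low correlation, their median correlation as a covariate, and the added spread contrasts were chosen only after the data were seen. Of the alternative values for the main results 168 kept their side of the threshold, or a count within 1.5 times the reported one, and 27 did not. A reversal was counted only where the sign changed and either value was called, and none was. Differences that were not called could change sign. The antiviral score difference for IFN+RBV against IFN went from 0.04 to -0.07171 without IFN replicate 4. In IFN against untreated patients (277 genes, 9 lists), array weights called 489 genes (261 shared), a minimum size of 1 left 110 and a Wilcoxon test 173; 4 lists passed with the median over members and 5 with camera. In IFN+RBV against RBV patients (157 genes, 8 lists), array weights called 378 (157 shared), a minimum size of 1 left 92, and 5 lists passed with the median and 4 with camera. With cell marker covariates 10 lists passed, and with the correlation covariate 11. The overlap of 96 genes became 153 with array weights and 53 with the minimum size. In RBV against untreated patients (1 gene) the count was 0 with no filter, quantile normalization, cell marker covariates, probe sets counted singly, only the groups compared, without the 7 arrays and with the correlation covariate, 2 by Wilcoxon and 405 with array weights. Weights of the 7 arrays ran from 0.132 to 0.680 and of the other 45 from 0.553 to 2.21. Of 100 splits with weights estimated anew, 30 called as many (real value 405, highest other 7699), so chance is not excluded for that count. For ribavirin averaged (0 genes, 0 lists), the mean of probe sets called 1 gene and array weights 272, and class I passed as 1 list without the 7 arrays (-0.26, adjusted p = 0.0351) and with the covariate (-0.24, adjusted p = 0.0453). IFN+RBV against IFN and the interaction stayed at 0 genes and 0 lists in every alternative run. A minimum size, camera and the groups compared alone give fewer genes or another test by construction; for the rest the cause was not tested.

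With each array left out in turn, IFN against untreated gave 197 (without IFN replicate 14) to 450 genes (without IFN replicate 4, the only array to move it by over 1.5 times) and 7 (without IFN replicate 13) to 10 lists (without untreated replicate 4). RBV against untreated gave 0 to 1 genes and 0 lists, with 0 genes without any of 16 of 26 arrays: untreated replicates 3, 6, 10, 11, 12, 13, 14 and 15 and RBV replicates 1, 2, 3, 4, 6, 8, 9 and 10. IFN+RBV against RBV gave 129 to 224 genes and 7 to 11 lists. Ribavirin averaged gave 0 to 1 genes (1 without untreated replicate 5). The antiviral score difference ranged from 1.178 to 1.366 for IFN against untreated, -0.2534 to -0.07112 for RBV against untreated, 1.375 to 1.548 for IFN+RBV against RBV, -0.07171 to 0.1197 for IFN+RBV against IFN, -0.1215 to -0.01562 averaged and 0.09952 to 0.2933 for the interaction, on 1 side of the threshold each time. The spread differences ranged from -0.2271 to -0.09676 (RBV minus untreated) and -0.1785 to -0.03253 (IFN+RBV minus IFN). Among single list scores 2109 alternatives kept their side, 17 gained and 28 lost a call. Among named genes 8176 kept their side, 66 gained and 61 lost a call. None changed sign where either value was called. Without the 7 arrays 192 of the 277 and 147 of the 157 genes were called. The planned RNA quality covariate from 3-prime and 5-prime control probe sets was not run, because 0 such probe sets are in the table used here. Signal over background limits genes of low log2 value, among them the bile duct keratins.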

Other observations

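The comparison of peginterferon averaged over ribavirin, and the genes it names, were chosen after the data were seen; the tests of random splits, of correlations with the antiviral score and of further clock genes were set down before their results.

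Averaged over patients without and with ribavirin, peginterferon moved 573 genes by limma, 397 higher and 176 lower, of which 268 (152 higher and 116 lower) had been called in neither group of patients alone. Among genes already called, the DNA-binding factor ETV7 rose by 1.84 (SE 0.270, adjusted p = 3.75e-06), the checkpoint ligand gene CD274 by 1.74 (SE 0.285, adjusted p = 2.67e-05) and ATP10A by 2.42 (SE 0.290, adjusted p = 6.58e-08). Newly called in the fixed lists were SOCS3 at 0.95 (adjusted p = 0.0083), IRF9 at 0.53 (adjusted p = 0.0115), the epithelial genes EPCAM at 1.66 (adjusted p = 0.0373), SOX9 at 1.0 (adjusted p = 0.0333) and CFTR at 1.12 (adjusted p = 0.0379), the bile acid repressor NR0B2 at -0.56 (adjusted p = 0.012) and IMPDH2 at -0.32 (adjusted p = 0.0405). Without the 7 arrays of low correlation CFTR and IMPDH2 lost the call (adjusted p = 0.0892 and 0.0955).

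Further single genes were called in the same averaged comparison. GOLM1, a Golgi protein gene of injured hepatocytes, rose by 1.10 (SE 0.247, adjusted p = 0.00346) and DCDC2, a gene of primary cilia in bile ducts, by 1.20 (SE 0.291, adjusted p = 0.00794). Large falls were those of MROH2A at -1.85 (SE 0.365, adjusted p = 0.000686), the adenylate cyclase ADCY1 at -1.58 (SE 0.393, adjusted p = 0.01) and the mitochondrial calcium-binding protein gene EFHD1 at -1.66 (SE 0.444, adjusted p = 0.0206). DHRS2, a dehydrogenase gene, fell by 2.0 (adjusted p = 0.0243) and lost the call without the 7 arrays (adjusted p = 0.0603).

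Random splits of the same arrays were fitted to ask whether the counts of called genes could arise by chance. Chance is argued against for IFN against untreated patients, where 1 of 100 splits, the real one, called as many genes (real value 277, highest other 97). The same holds for IFN+RBV against RBV patients, again 1 of 100 (real value 157, highest other 2). With 100 splits no smaller share can be seen, so chance is not excluded. In RBV against untreated patients, 3 of 100 splits, the real one included, reached the real count of 1 (highest other 2199). For the counts of 0 the splits decide nothing, since every split calls at least 0 genes and so 100 of 100 count as reaching them: the highest other was 184 for IFN+RBV against IFN, 2988 for ribavirin averaged and 1 for the interaction. A random split that called 2988 genes where the real one called 0 points to a structure of the samples that the groups do not explain.

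Circadian genes were among those lower after peginterferon, which a different time of day of the biopsies may explain, if those taken 6 h after an injection fell later in the day. PER3 fell by 0.98 (SE 0.237, adjusted p = 0.00806), CIART by 1.01 (SE 0.233, adjusted p = 0.00448) and TEF by 0.70 (SE 0.123, adjusted p = 9.77e-05) in the averaged comparison. If time of day were the cause, other clock output genes should fall relative to the oppositely timed BMAL1, NPAS2 and CLOCK. They differed by -0.8388 (SE 0.170, 95% interval -1.18 to -0.498, permutation p = 2e-05), by -0.91 (p = 0.00087) without and by -0.77 (p = 0.0031) with ribavirin. Most of this contrast came from the BMAL1 arm, which differed by 0.59 (p = 0.00068), while the output genes by themselves differed by -0.24 (SE 0.0801, p = 0.00309), by -0.17 (p = 0.16) without and by -0.32 (p = 0.00426) with ribavirin. DBP, HLF and CRY2 differed by -0.18, -0.19 and -0.27 and BHLHE41 by 0.17, none called (adjusted p = 0.438, 0.689, 0.296 and 0.919). NR1D2 fell by 0.54 (adjusted p = 0.00181), BMAL1 rose by 0.85 (adjusted p = 0.0406) and NPAS2 by 0.75 (adjusted p = 0.0217). PER2 differed by -0.46 (adjusted p = 0.205) and CLOCK by 0.18 (adjusted p = 0.594), and PER1 and NR1D1 were not measured by a tested probe set. These genes share the arrays and the clock loop of PER3, CIART and TEF, so their shift is not independent support for time of day. NR1D2, BMAL1 and NPAS2 also passed the threshold in the same averaged comparison as PER3, CIART and TEF. The contrast is therefore not a fresh test, and its p-value does not measure one. A direct effect of interferon on the clock would give the same values and stays open, and the time of biopsy is not given in the sources used here. If the hour of biopsy differed between the groups, part of the called genes in both peginterferon comparisons could follow it.

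The antiviral score varied between untreated patients (SD 0.77, n = 15), and 2 explanations were tested among 8 correlations over the 4 groups. That a correlation counts against an explanation only through its interval was decided after the values were seen. Lymphocyte content could raise it, but the score had a Pearson correlation of -0.0148 with the T cell marker score (permutation p = 0.958, adjusted p = 0.958, 95% interval -0.523 to 0.501; Spearman's rho -0.0143, permutation p = 0.964, adjusted p = 0.964; r = -0.0779 without the 2 patients farthest from the median), which leaves a moderate relation open. Array quality could also contribute: the correlation with the median correlation of the array was 0.422 (permutation p = 0.116, adjusted p = 0.464; rho 0.400, permutation p = 0.14, adjusted p = 0.435; r = 0.285 without the 2 farthest), which decides neither way at this number of patients. In the IFN group this correlation was 0.791 (permutation p = 0.00314, adjusted p = 0.0251), but rho was 0.398 (permutation p = 0.16, adjusted p = 0.435) and r fell to 0.256 without the 2 farthest arrays, so it rests on those arrays.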
